A study of Canis lupus familiaris with 12 samples.

How the data were processed

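Polyadenylated RNA was sequenced from 12 samples of immortalized canine myoblasts, the precursor cells of skeletal muscle, grown as a cell line. Per the labels' protocols, the cells had been transduced with pCW57.1, a lentiviral vector that drives an inserted gene when doxycycline is present. The insert was human DUX4, canine DUXC, a DUXC isoform called DUXC-ALT, or luciferase as the negative control. The samples formed 4 groups of 3 libraries each, grouped by the insert that the genotype tag of each sample names. Replicate numbers are those in the titles. Libraries were made with the TruSeq RNA v2 kit and pooled 14 to a lane, per the labels' protocols. The treatment protocol gives 1 ug/ml doxycycline for 24 h for every sample, whereas the treatment tag of the luciferase samples says that they received none. The tag of the other samples names doxycycline. The labels do not settle this, so each comparison with luciferase may also compare doxycycline with its absence. The comparisons among DUXC, DUXC-ALT and DUX4 do not carry this difference. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

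The submitters' processing notes name the canFam3 genome build, CASAVA, TopHat2 2.1.0, Bowtie2 2.2.6 and DESeq2, with no role or order. The counting tool, its treatment of strand and its treatment of reads that match several places are not given in the sources used here. Reads from near-identical genes, overlapping genes or repeat copies may therefore be split or shared between rows. The authors deposited 12 tables, each holding the 3 luciferase libraries and the 3 libraries of 1 factor. The 3 gene tables and 3 repeat tables of raw counts, as deposited, hold whole-number read counts per row. The other 6 deposited tables hold a normalized signal made by the authors. Each of those values equals the raw count divided by 1 factor per library, with a largest relative gap of 5.4e-16. These factors were set within each table. The authors' repeat factors averaged 2.01 times the luciferase value in the DUX4 libraries, 1.72 times in the DUXC libraries and 0.991 times in the DUXC-ALT libraries. The normalized repeat values thus have most of any overall shift of repeat counts divided out. Tests here used the raw counts, and the normalized tables served only for this check.

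The tables as used here carry no names for gene rows or repeat rows. A row is therefore cited by its number in its table, and no gene symbol, position or repeat class is given. The supplied list of RefSeq names, built on the UU_Cfam_GSD_1.0 assembly, could not be matched to any row. Gene lists and repeat groups fixed before the data were examined were not tested, nor were rows of the expressed factors themselves. The gene tables held 17070 rows for DUX4, 17075 for DUXC and 15628 for DUXC-ALT. The repeat tables held 726, 717 and 683 rows. The smallest row total was 7 reads in every table, so rows with fewer reads over the 6 libraries of a table were absent from it. To set factors against each other, tables were joined through the luciferase counts. Rows with at least 7 luciferase reads occur in every table in the same order with the same luciferase counts. This gave 14736 joined gene rows, of which 13106 had a combination of luciferase counts found in no other row, and 654 joined repeat rows. Rows with fewer luciferase reads could not be joined, so comparisons between factors leave out genes that were silent in luciferase cells.

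Gene counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr, a robust quasi-likelihood fit and Benjamini-Hochberg adjustment at 0.05. Each fit used only the 6 libraries compared. A row past the threshold is called raised or lowered. Repeat counts were tested in the same way with effective library sizes taken from the gene counts of the same libraries, because repeats may change as a whole. CPM were computed on the total gene count of each library. Single values per library were compared with a 2-sided exact permutation test, which cannot go below p = 0.1 for 3 against 3 libraries, adjusted over 25 such tests. Where a group held no count, the fold was computed against 3 counts over the group. Where it held 1 to 3 counts, an exact Poisson interval at 95% is given. Both cover counting error only. The overlap of comparisons that share the luciferase libraries was set beside the overlap of independent lists and beside 10 simulated draws of unchanged groups. In a draw all libraries, luciferase included, came from the luciferase means with a single fixed spread. A state of the real luciferase libraries therefore cannot appear in them.

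The rule for named rows was fixed before the data were examined. It took the largest rises and falls among rows past the threshold. A gene row also needed a mean of at least 1 CPM in the higher group and no overlap between the groups. A repeat row needed a mean of at least 20 counts in the higher group. The rule had allowed more rows than are named here. As rows have no names, at most 2 risen and 2 fallen rows are given per comparison. The steps were tested on simulated data with known changes. For DUX4 against luciferase, over 13496 simulated gene rows, 94% of rows changed 1.5-fold and 100% of rows changed 2-fold upward were called, and 1.99% of calls were false. For DUXC-ALT against luciferase, over 12797 rows, the shares were 88% and 100%, with 3.02% of calls false. For each fold only 50 gene rows were changed, all with a mean of at least 20 counts, at a single fixed spread. These rates do not carry over to genes of fewer counts, or to data where far more genes change. Alternatives were other scaling factors, no filter, DESeq2 1.42.0, the replicate number as a block, a single fit over all 4 groups, a test against a 2-fold change, scaling on the repeats themselves and leaving out each library. The repeat ratio without the most abundant repeat row, the choice of genes lowered with DUXC-ALT without 1 luciferase and 1 DUXC-ALT library, and luciferase libraries split so that no 2 comparisons share one, were alternatives chosen after seeing the data. In the split, a factor tested against 1 luciferase library assumes that this library varies like the others. Figures and tests of single values were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.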

Results

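Transcripts of canine myoblasts carrying inducible human DUX4, canine DUXC, DUXC-ALT or luciferase were counted in 12 libraries, with 3 libraries per group. DUX4 and DUXC are double homeobox transcription factors, and DUXC-ALT is an isoform of DUXC. The series asks how far the canine factor and its isoform resemble human DUX4 in what they switch on in muscle cells. Gene counts per library ranged from 15556477 in DUX4 replicate 3 to 20591033 in luciferase replicate 3. Repeat counts ranged from 524876 in DUXC-ALT replicate 3 to 1226444 in DUX4 replicate 2. Replicates of a group correlated at 0.998 across genes on a log scale. Their counts differed by 1.40 to 2.51 times the sampling noise, as chi-square per degree of freedom, so no 2 libraries were copies of each other.

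Human DUX4 raised 5237 and lowered 4881 of 13629 tested genes relative to luciferase. TMM scaling holds the median log2 fold of genes near 0 (0.005 here, 0.0007 with DUXC and 0.005 with DUXC-ALT). The near-even numbers of rises and falls thus depend in part on the scaling. The rises were larger than the falls, with 2105 genes raised and 615 lowered by more than 2-fold, and 657 raised and 21 lowered by more than 8-fold. Gene row 2046 of the DUX4 table rose from 0 counts in every luciferase library to 890, 969 and 868 counts, at least 1035-fold higher, at 54.9 ± 1.84 CPM (SD, n = 3; edgeR adjusted p = 3.31e-73). Gene row 13826 rose from 0.165 ± 0.109 to 717.6 ± 22.2 CPM (SD, n = 3), a log2 fold change of 12.06 ± 0.08 (SE; edgeR adjusted p = 5.23e-111). Among the falls, gene row 319 went from 5.12 ± 1.001 to 0.0821 ± 0.0405 CPM (SD, n = 3), a log2 fold change of -5.88 ± 0.36 (SE; edgeR adjusted p = 2.09e-28). Gene row 8589 went from 77 luciferase reads to 1 read, a ratio of 0.0148 with an exact Poisson interval of 0.000369 to 0.0847. Both rows were also nearly absent with the other factors. Row 319 had 4 reads with DUXC and 1 with DUXC-ALT, and row 8589 had 0 and 1. These differences from luciferase are thus not particular to DUX4, and the doxycycline label differs in the same way. Genes of low expression held most of the large rises. Of the genes raised by more than 2-fold, 1211 lay in the lowest of 3 equal groups by mean expression, 480 in the middle and 414 in the highest. In all, 80 genes had no count in any luciferase library and at least 1 CPM in every DUX4 library, with a median of 2.48 CPM. No gene, that is 0, showed the opposite. A luciferase count of 0 allows up to 0.0531 CPM over the group.

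Canine DUXC changed a similar number of genes, with 5325 raised and 5121 lowered of 13693 tested. More than 2-fold changes comprised 2207 rises and 681 falls, and 739 genes rose by more than 8-fold. Gene row 16660 of the DUXC table rose from 0 counts to 656, 664 and 638 counts, at least 687-fold higher, at 36.5 ± 1.56 CPM (SD, n = 3; edgeR adjusted p = 5.25e-39). Gene row 11303 rose from 0 to 33.9 ± 2.04 CPM (SD, n = 3), at least 638.5-fold higher (edgeR adjusted p = 3.96e-38). Gene row 8676 fell from 77 luciferase reads to 0, at least 24.7-fold lower, and is the joined partner of row 8589 of the DUX4 table. Gene row 12107 fell from 381 reads to 2, a ratio of 0.00552 with an exact Poisson interval of 0.000666 to 0.0201. That gene had 22 reads with DUX4 and 2 with DUXC-ALT, and the gene of row 8676 had 1 read with DUXC-ALT. Neither fall is thus particular to DUXC. Of the genes raised by more than 2-fold, 1308 lay in the lowest of 3 equal groups by mean expression. In all, 104 genes had no luciferase count and at least 1 CPM in every DUXC library, with a median of 2.48 CPM, and 1 gene showed the opposite.

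The isoform DUXC-ALT called 3283 genes raised and 3292 lowered of 12821 tested, but few of the rises were large. Only 108 genes rose by more than 2-fold, against 467 that fell by that much, and 2 rose and 41 fell by more than 8-fold. Of the 467 large falls, 384 lay in the lowest of 3 equal groups by mean expression, 55 in the middle and 28 in the highest. Gene row 8680 of the DUXC-ALT table rose from 0.0874 ± 0.0260 to 1.499 ± 0.438 CPM (SD, n = 3), a log2 fold change of 3.90 ± 0.48 (SE; edgeR adjusted p = 8.79e-11). Gene row 12108 rose from 0.0889 ± 0.0320 to 1.37 ± 0.187 CPM (SD, n = 3), a log2 fold change of 3.79 ± 0.48 (SE; edgeR adjusted p = 2.32e-10). Gene row 5572 fell from 2.17 ± 0.392 CPM to 0 counts, at least 40.5-fold lower, and gene row 498 fell from 1.75 ± 0.0868 CPM to 0 counts, at least 32.6-fold lower. Row 5572 was nearly absent with the other factors too, at 8 reads with DUX4 and 3 with DUXC against 122 with luciferase. Row 498, joined to row 523 of the DUXC table, stood at 7.25 ± 1.19 CPM with DUXC and 1.33 ± 0.357 CPM with DUX4. With DUXC-ALT, 0 genes went from no luciferase count to at least 1 CPM in all 3 libraries, and 2 showed the opposite. The 80 genes that appeared with DUX4 and the 104 that appeared with DUXC all had fewer than 7 reads over the luciferase and DUXC-ALT libraries together.

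**Figure D1:**
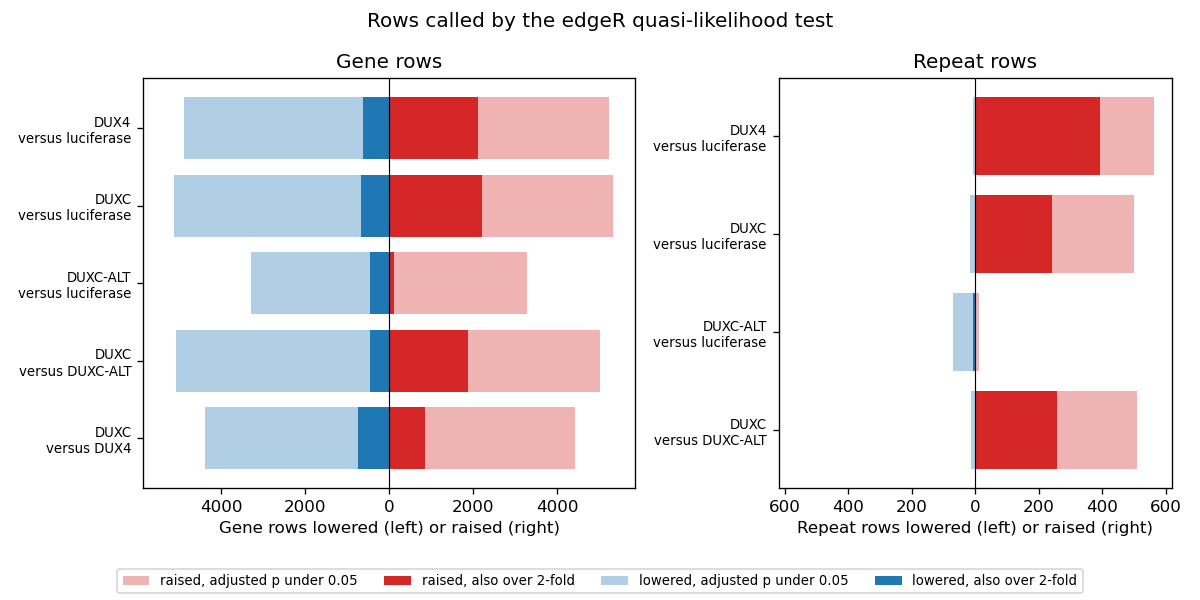
Number of gene rows (left panel) and repeat rows (right panel) called by edgeR's quasi-likelihood test in each comparison, with lowered rows to the left of 0 and raised rows to the right; dark bars are those that also changed by more than 2-fold. DUXC-ALT has 108 gene rows raised by more than 2-fold, against 2105 with DUX4 and 2207 with DUXC.

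DUXC and DUXC-ALT were compared directly over the joined genes, where the doxycycline label does not differ. DUXC was higher than DUXC-ALT for 5026 and lower for 5078 of 13148 tested genes, with 1878 higher and 467 lower by more than 2-fold. Gene row 7744 of the DUX4 table stood at 727.7 ± 16.8 CPM with DUXC and 0.128 ± 0.134 CPM with DUXC-ALT (SD, n = 3), a log2 difference of 12.45 ± 0.08 (SE; edgeR adjusted p = 3.57e-65). The same gene stood at 93.0 ± 4.76 CPM with DUX4 and 0.244 ± 0.0621 CPM with luciferase. Gene row 1532 stood at 682.1 ± 14.5 CPM with DUXC, 362.1 ± 13.4 with DUX4, 0.227 ± 0.118 with DUXC-ALT and 0.327 ± 0.135 with luciferase (SD, n = 3). In the other direction, gene row 11110 stood at 11.4 ± 1.73 CPM with DUXC and 76.5 ± 3.64 CPM with DUXC-ALT, a log2 difference of -2.72 ± 0.07 (SE; edgeR adjusted p = 1.22e-39). This gene stood at 43.4 ± 3.53 CPM with luciferase and 46.6 ± 1.17 CPM with DUX4. Gene row 2496 stood at 0.2996 ± 0.0747 CPM with DUXC and 2.21 ± 0.132 CPM with DUXC-ALT (SD, n = 3), a log2 difference of -2.84 ± 0.33 (SE).

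DUXC and DUX4 also differed directly, at 4412 genes higher and 4398 lower with DUXC of 13324 tested. The differences of more than 2-fold numbered 851 higher with DUXC and 737 higher with DUX4. Gene row 2663 of the DUX4 table stood at 999.8 ± 37.5 CPM with DUX4 and 20.6 ± 0.630 CPM with DUXC, against 0.223 ± 0.147 CPM with luciferase (SD, n = 3). The log2 difference was -5.60 ± 0.04 (SE; edgeR adjusted p = 3.48e-73). Gene row 211 stood at 148.1 ± 3.19 CPM with DUX4, 1.18 ± 0.126 CPM with DUXC and 2.41 ± 0.243 CPM with luciferase (SD, n = 3). Gene row 347 had 193 reads with DUXC and 0 with DUX4, at least 58.8-fold higher with DUXC, and 9 reads with luciferase. Gene row 349 had 303 reads with DUXC and 1 with DUX4, a ratio of 280.3 with an exact Poisson interval of 49.9 to 11110.

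The genes moved by DUX4 and by DUXC overlapped more than independent lists would. Of 13011 joined genes tested against luciferase with both, 3376 were raised in both and 3676 lowered in both. Independent lists of those lengths would share 1690 and 1920. Log2 fold changes correlated at 0.77 across genes, which are not independent replicates, with a covariance of 0.818. Unchanged groups simulated with shared controls, which were simulated too, gave a correlation of 0.49 and a covariance of 0.00772. They gave 0 shared calls, which the lack of any change made nearly certain, so that count is no baseline for the overlap. Of 1560 joined genes that DUX4 raised by more than 2-fold, 88.2% were also raised with DUXC, by a median log2 fold change of 1.30, and 986 of them by more than 2-fold. The overlap of all calls with DUXC-ALT was smaller. DUXC and DUXC-ALT shared 1264 rises and 1835 falls over 12745 genes, against 1146 and 1322 for independent lists, with a correlation of 0.25 and a covariance of 0.111. The simulated values for that pair were 0.51 and 0.00796. DUX4 and DUXC-ALT shared 1383 rises and 1969 falls over 12752 genes, against 1139 and 1259. Of the 2105 genes that DUX4 raised by more than 2-fold, 1321 were joined and tested with DUXC-ALT. Of these, 22.5% were raised and 23.6% lowered with DUXC-ALT, with a median log2 fold change of -0.00. Of the 2207 that DUXC raised by that much, 1360 were joined and tested, with 23.2% raised and 22.2% lowered with DUXC-ALT and a median of 0.01. Of the 615 genes that DUX4 lowered by more than 2-fold, 76.1% were also lowered with DUXC, with a median of -0.85, and 79.8% with DUXC-ALT, with a median of -0.76. Of the 681 that DUXC lowered by that much, 84.6% were also lowered with DUX4, with a median of -0.82, and 66.2% with DUXC-ALT, with a median of -0.49. With the luciferase libraries split, 2 for 1 factor and 1 for the other, so that no library was shared, DUX4 and DUXC shared 2970 to 3038 rises and 3301 to 3413 falls over the 6 splits, at 2.04 to 2.09 and 1.95 to 2.02 times independent lists. The covariance was 0.820 to 0.851. DUXC and DUXC-ALT shared 1.03 to 1.12 times as many rises and 1.41 to 1.53 times as many falls as independent lists, and DUX4 and DUXC-ALT 1.15 to 1.23 and 1.56 to 1.68 times. With genes chosen on 1 part of the luciferase libraries and measured against the other, 77.4% to 85.2% of the genes that DUX4 raised by more than 2-fold were also raised with DUXC, and 15.9% to 20.8% with DUXC-ALT. Of the genes that DUX4 lowered by that much, 63.8% to 73.2% were also lowered with DUXC, with medians of -0.87 to -0.77, and 66.6% to 77.1% with DUXC-ALT, with medians of -0.77 to -0.67, so these shares do not rank the 2 factors. Of those that DUXC lowered, 73.2% to 80.2% were also lowered with DUX4 and 54.5% to 62.1% with DUXC-ALT. These splits were added after seeing the data, and the doxycycline label is still shared in them.

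**Figure D2:**
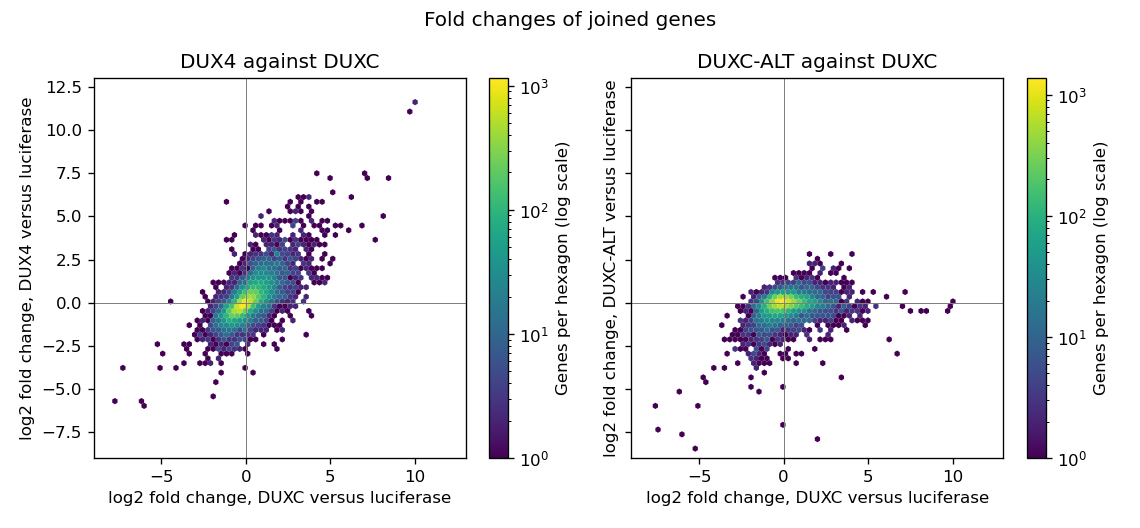
Log2 fold change against luciferase with DUX4 (left) and DUXC-ALT (right) on the vertical axis and with DUXC on the horizontal axis, over 12712 joined genes tested with all 3 factors; colour is the number of genes per hexagon on a log scale. The DUX4 cloud follows the diagonal, with a correlation of 0.77 over the genes tested with that pair, and the DUXC-ALT cloud stays near 0 where DUXC is high.

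Most repeat rows rose relative to genes with DUX4 and with DUXC, and most were higher with DUXC than with DUXC-ALT. Repeat counts per 100 gene counts were 3.49 ± 0.0447 with luciferase, 6.94 ± 0.344 with DUX4, 5.44 ± 0.471 with DUXC and 3.19 ± 0.358 with DUXC-ALT (SD, n = 3). DUX4 stood at 1.99 times the luciferase level, DUXC at 1.56 times and DUXC-ALT at 0.913 times. In the exact permutation tests DUX4 and DUXC gave p = 0.1, the smallest that 3 against 3 libraries can give, with 0.132 after adjustment over 25 tests, and DUXC-ALT gave p = 0.3. A single repeat row, number 335 of the DUX4 repeat table, held 44.5% ± 0.662 of luciferase repeat counts (SD, n = 3). It varied between DUXC libraries from 1.35 to 2.05 per 100 gene counts. Without that row the ratios to luciferase were 2.43 for DUX4, 1.88 for DUXC and 1.02 for DUXC-ALT, and 1.85 for DUXC over DUXC-ALT, a calculation added after seeing the data.

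**Figure D3:**
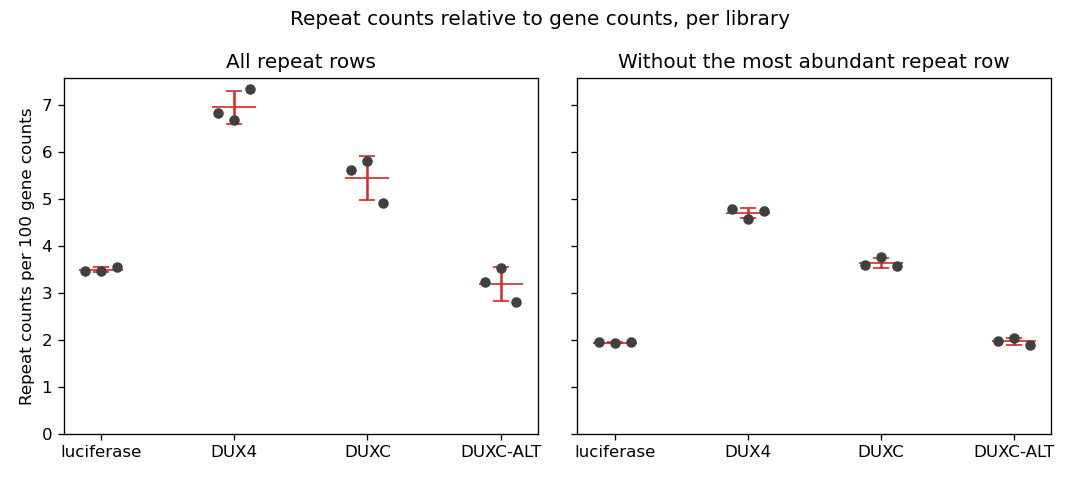
Repeat counts per 100 gene counts in each library (points), with the group mean and SD of 3 libraries (red lines), over all repeat rows (left) and without the most abundant repeat row (right). Every DUX4 and DUXC library lies above every luciferase and DUXC-ALT library in both panels.

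Row by row, with scaling from genes, DUX4 raised 564 and lowered 7 of 617 tested repeat rows, 392 of them raised by more than 2-fold, and the median log2 fold change was 1.21. DUXC raised 500 and lowered 17 of 605, or 9 lowered with DESeq2, with a median of 0.80. DUXC-ALT raised 10 and lowered 70 of 554, with a median of -0.07, but leaving out 1 library gave 3 to 12 raised and 39 to 83 lowered, and DESeq2 gave 4 and 42 of the 259 rows for which it gave an adjusted p. Directly compared, DUXC exceeded DUXC-ALT in 509 of 598 repeat rows and lay below it in 13, with a median of 0.90. Repeat row 35 of the DUX4 repeat table rose from 0 counts to 656, 730 and 644 counts, at least 769.7-fold higher, and row 5 went from 3 reads to 2284, a ratio of 864.8 with an exact Poisson interval of 295.6 to 4197. With DUXC, repeat row 235 of its table rose from 3 reads to 2552, a ratio of 893.9 with an exact Poisson interval of 305.5 to 4337. Repeat row 686 rose from 0.375 ± 0.0735 to 7.44 ± 1.36 CPM with DUXC and stood at 10.2 ± 0.832 CPM with DUX4 and 0.273 ± 0.114 CPM with DUXC-ALT (SD, n = 3). Against DUXC-ALT, that row was higher with DUXC by 4.79 ± 0.25 on the log2 scale (SE; edgeR adjusted p = 2.99e-25), and repeat row 504 of the DUX4 repeat table by 5.15 ± 0.25. By more than 2-fold, 1 repeat row fell with DUX4 and 1 with DUXC, and 8 fell and 0 rose with DUXC-ALT. All of these falls lay in the lowest of 3 equal groups by mean expression, where counts are low. That group had a median of 1.19 CPM for DUXC-ALT against luciferase. Repeat row 80 of the DUX4 repeat table changed by a log2 fold of -1.61 ± 0.34 with DUX4, -1.90 ± 0.29 with DUXC and -1.29 ± 0.30 with DUXC-ALT (SE). Repeat row 67 of the DUXC-ALT repeat table changed by -1.60 ± 0.19 with DUXC-ALT (SE; edgeR adjusted p = 4.66e-12). Its repeat row 406 rose by 0.65 ± 0.22 (SE; edgeR adjusted p = 0.0281), a call lost without luciferase replicate 1 or 3 or DUXC-ALT replicate 2 or 3. These directions are relative to genes. Scaled on the repeats themselves, raised and lowered rows numbered 215 and 207 with DUX4, 205 and 172 with DUXC and 19 and 29 with DUXC-ALT, and 194 and 193 for DUXC over DUXC-ALT. The raised share of calls went from 98.8% to 51.0% with DUX4, from 96.7% to 54.4% with DUXC, from 12.5% to 39.6% with DUXC-ALT and from 97.5% to 50.1% for DUXC over DUXC-ALT. The repeat rows named here kept their direction under that scaling.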

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

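The tests of the most abundant repeat row, of a few induced repeat rows, of doxycycline, of carry-over with its final bound and of a shared state of the luciferase libraries were chosen after the result was seen. The test of low counts in held-out libraries was added after the falls were seen, with its bound set before its values were. For each of the 9 comparisons of gene or repeat rows, 1 of the 10 splits of its 6 libraries, the real one, gave as many calls. With 10 splits no share under 0.05 is possible, so this does not decide on chance. For genes, the real splits gave 10118 calls for DUX4, 10446 for DUXC and 6575 for DUXC-ALT against luciferase, 10104 for DUXC against DUXC-ALT and 8810 for DUXC against DUX4. The highest of the other splits gave 0 edgeR calls in each, with at most 168 genes at an unadjusted p under 0.05; DESeq2 was not run on the splits. For repeats, the real splits gave 571, 517, 80 and 522 calls. The highest other split gave 1 call, for DUXC-ALT against luciferase, and 0 elsewhere, with at most 34 rows at an unadjusted p under 0.05.

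Some genes moved in opposite directions with different factors against the same luciferase libraries. All of these also passed the direct test between the factors, which their choice by opposite calls made nearly certain, so that test adds no evidence of its own. There were 415 genes raised with DUX4 and lowered with DUXC, and 413 raised with DUXC and lowered with DUX4. Both changes exceeded 2-fold for 5 and 19 of them. There were 919 genes raised with DUXC and lowered with DUXC-ALT, of which both changes exceeded 2-fold for 55, and 1262 raised with DUXC-ALT and lowered with DUXC, of which both changes exceeded 2-fold for 0, by edgeR at an adjusted or an unadjusted p under 0.05 and by DESeq2. Independent lists would give 3604 opposite calls for DUX4 and DUXC, where 828 were seen, and 2467 for DUXC and DUXC-ALT, where 2181 were seen. No such value was computed for changes over 2-fold, where the lists differ in length. DUXC raised 1360 joined genes and DUXC-ALT lowered 465 by that much, whereas DUXC-ALT raised 98 and DUXC lowered 681. The counts of 55 and 0 therefore do not rank the 2 directions.

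Repeat counts rose relative to gene counts with DUX4 and DUXC, and without the most abundant repeat row the ratio was still 1.88 for DUXC and 2.43 for DUX4, so that row alone does not account for it, and a median log2 fold of 0.80 over all tested repeat rows with DUXC argues against a few induced rows. The ratio of 1.02 with DUXC-ALT, which carries the same doxycycline label, argues against doxycycline. Carry-over of DNA or unspliced RNA, larger in DUX4, stays open: edgeR called 54.3% of 619 tested repeat rows higher with DUX4 than with DUXC, and the 7.43% called higher with DUXC may be specific to DUXC on top of it. That share passed a bound of 5% set before it was seen, but the bound assumed a repeat profile of carry-over that no table measures, so it excludes nothing. Activation of many repeats by DUX4 and DUXC is a hypothesis beside it.

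DUXC-ALT lowered 467 genes by more than 2-fold, most of them of low expression. Noise of low counts would not recur in libraries left out of the choice of genes, but among genes chosen without 1 luciferase and 1 DUXC-ALT library the median log2 fold in that held-out pair was -1.33, -1.36 and -1.39, on counts with 0.5 added, and at least 97.5% of the genes were lower there. A state of the luciferase libraries, such as missing doxycycline, would by itself lower the same genes by the same amount with every factor. Over the 465 of these genes with a DUXC value, the log2 fold with DUXC exceeded that with DUXC-ALT by a median of 0.84, with quartiles of 0.20 and 1.80. Against each held-out DUXC-ALT library the median was 0.67 to 0.87, with lower quartiles from -0.0005 to 0.134. With DUX4 the excess over DUXC-ALT had a median of 0.83 and quartiles of -0.07 and 2.1. The falls were thus unequal across the factors over the genes as a set. DUXC and DUX4 raising some of these genes on top of such a state would give the same excess. The medians therefore do not exclude the state as the whole cause of the falls with DUXC-ALT. It also stays open because 233 of the 467 genes were called lower with both DUX4 and DUXC. Every factor library also differs from luciferase in its doxycycline label. Among those 233 genes the median excess was only 0.28 with DUXC and 0.05 with DUX4, so for them the state stays open as the main cause. In the other 234, set apart by those same calls, the median excess was 1.64 and 1.8.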

How the results depend on the processing

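The repeat ratio without the most abundant row, the choice of genes lowered with DUXC-ALT without 1 luciferase and 1 DUXC-ALT library, and the split luciferase libraries were chosen after seeing the data, and the other alternatives before. With split libraries all 36 counts of calls shared by 2 factors stayed within 1.5 times, and 3 of 12 counts alike with all 3 factors fell by more. Genes over 2-fold lower with DUXC-ALT, chosen on 4 libraries, numbered 480, 513 and 489. Other size factors also left the median log2 fold of genes near 0, at 0.008 with DUX4 and 0.015 with DUXC against luciferase. The single fit over all groups used only joined rows, so it left out genes with fewer than 7 luciferase reads. Under that fit, other size factors, no filter, DESeq2, the replicate block and leaving out any library, gene counts of calls stayed within 1.5 times. They fell when tested against a 2-fold change, which is a stricter question: 1710 raised and 357 lowered with DUX4, 1771 and 356 with DUXC, 36 and 214 with DUXC-ALT, 1406 and 219 for DUXC over DUXC-ALT, and 556 and 430 for DUXC over DUX4. The single fit over all groups gave 3738 genes higher and 5245 lower with DUXC than with DUX4, a raised share of 41.6% of calls against 50.1% in the main fit, with a median log2 fold of -0.07, so that balance depends on the fit. Against a 2-fold change, shared rises and falls numbered 692 and 120 for DUX4 and DUXC, 21 and 92 for DUXC and DUXC-ALT, and 16 and 89 for DUX4 and DUXC-ALT.

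Scaling on the repeats themselves gave 215 raised and 207 lowered repeat rows with DUX4, 205 and 172 with DUXC, 19 and 29 with DUXC-ALT, and 194 and 193 for DUXC over DUXC-ALT. By construction it centres the median log2 fold, which went from 1.21 to 0.03, from 0.80 to 0.01, from -0.07 to 0.01 and from 0.90 to 0.01. DESeq2 called 9 repeat rows lowered with DUXC, and 4 raised and 42 lowered with DUXC-ALT, where it gave an adjusted p for 259 rows against 554 in the main fit, so these counts do not compare as shares. Leaving out 1 library, repeat rows called with DUXC-ALT ranged from 3 to 12 raised and from 39 to 83 lowered. They were 5 and 46 without luciferase replicate 1, 5 and 44 without luciferase replicate 3 and 5 and 39 without DUXC-ALT replicate 1, and 3 rows were raised without DUXC-ALT replicate 2. Fewer libraries were tested there. Without the most abundant row the repeat ratio was 2.43 with DUX4 and 1.88 with DUXC.

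Replicate numbers gave no clear pairing of the libraries in most comparisons. Same-numbered libraries correlated between -0.05 and 0.02 for genes and between -0.12 and 0.05 for repeats in their deviations from the group mean. In 1 gene comparison, DUXC-ALT against luciferase, all 6 libraries correlated best with their own number. The correlations were only 0.011 to 0.017, so pairing there is not settled. The replicate block gave 5236 raised and 4887 lowered genes with DUX4 and moved no count of calls by over 1.5 times. Over the 36 named rows, 381 of 385 values under alternatives kept direction and call, 0 reversed, and 4 lost the call, all for repeat row 406 of the DUXC-ALT table, with adjusted p from 0.0907 to 0.148. DESeq2 gave no adjusted p for 3 further values. The gene list and repeat group tests, with their alternatives, were not run, as rows carry no names here. Depth limits rows of few reads, since rows under 7 reads per table are absent.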

Other observations

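The split of the luciferase libraries and the test of reads shared by adjacent genes were chosen after the result was seen, and the test of expression level before.

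Falls were shared by all 3 factors beyond the overlap of DUX4 and DUXC more than rises were. Of 12712 joined genes, 959 were raised with every factor and 1547 lowered. Independent lists would give 398.5 and 508.4, but much of that excess restates the overlap of DUX4 and DUXC: with the 3146 rises and 3676 falls they share here, DUXC-ALT calls independent of these would give 808.5 and 951.1. In 10 simulated draws of unchanged groups, with luciferase drawn too, the highest count was 0. The lack of any change made that nearly certain, so it is no baseline for these counts. With a different luciferase library for each factor, in 6 ways, 596 to 664 genes were raised with every factor, at 1.14 to 1.23 times the value for DUXC-ALT calls independent of the shared ones, and 1179 to 1215 were lowered, at 1.75 to 1.94 times. The doxycycline label is shared by the 3 comparisons in every case. The genes DUXC-ALT raised by more than 2-fold were mostly raised by the other factors too. Of 98 such joined genes tested with DUXC, 84 were raised with DUXC, by a median log2 fold of 1.40, and 1 was lowered. Of 100 tested with DUX4, 76 were raised, by a median of 1.19, and 2 were lowered. With such genes chosen on 1 part of the luciferase libraries and measured against the other, 61.3% to 74.8% were raised with DUXC and 62.1% to 68.2% with DUX4.

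The counts were less concentrated in the factor libraries than in luciferase. The most abundant gene row of each library held 2.81% ± 0.0744 of gene counts with luciferase, 1.87% ± 0.0304 with DUX4, 1.90% ± 0.0106 with DUXC and 1.94% ± 0.0147 with DUXC-ALT (SD, n = 3). The 100 most abundant rows held 31.6%, 27.2%, 27.8% and 28.5%. Each factor differed from luciferase at an exact permutation p = 0.1, the smallest possible here, or 0.132 adjusted over 25 tests. The doxycycline label differs in the same way in each of these comparisons, so an effect of the factors cannot be told apart from it.

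Fold changes of rows next to each other in the gene tables were weakly alike with DUX4 and DUXC. The correlation between neighbours was 0.0480 with DUX4 (permutation p = 1e-05, the smallest that 100000 permutations can give; 3e-05 adjusted over 3 tests), 0.0311 with DUXC (permutation p = 0.00149, adjusted 0.00224) and 0.00225 with DUXC-ALT (permutation p = 0.81). Rows are not independent replicates, and what orders them is not stated. Reads shared by adjacent overlapping genes would act on direct neighbours, but the mean correlation at distances of 2 to 5 rows was 0.0241 with DUX4 and 0.0269 with DUXC, which argues against that as the whole cause. With the mean of each expression decile removed, the correlation between direct neighbours was 0.0423 with DUX4 and 0.0230 with DUXC. The standard error was 0.00935 for DUXC, so a part from expression level cannot be told apart there. A shared response of neighbouring genes stays open, as a hypothesis.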
